A study of Homo sapiens with 9 samples.

How the data were processed

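Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed in 2 established prostate cell lines, with 1 library per factor. Libraries were constructed with the Illumina ChIP-seq kit, per the labels' protocols. Of the 9 libraries, the 6 with an antibody against a transcription factor or against FLAG on an expressed FLAG fusion have a peak list here. The 2 input libraries and the FLAG control in RWPE-1 have no list that was analysed here. Samples were assigned to groups from their titles.

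The lists hold 3143 ETV4, 2973 JUND, 2180 ETS1, 8070 GABPA, 2314 FLAG-ERG and 8736 FLAG-ETV1 regions, called peaks here. The authors deposited each list as 3 columns without a header: a chromosome and the start and end of a called region. The genome build is hg18, per the labels. The peak caller, the aligner, the control library used in calling and the threshold are not given in the sources used here. The deposited lists hold no score, height or p-value, so every region counts once whatever its strength, and the depth behind each region is unknown. Start positions were read as counted from 0, as in the BED format, and are printed counted from 1. No gene annotation or sequence of hg18 was used here, since the gene table at hand is on another build. The comparisons of promoter shares, of sequence motifs and of gene lists, fixed before the data were examined, were therefore not run, and regions are named by position.

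Peaks of different lists were called shared where they overlapped by at least 1 bp. No list repeated a region and no list held overlapping regions. Each share of a list carries a Wilson 95% binomial interval, which covers counting error only. For each of the 15 pairs of lists, the number of shared peaks was compared with 1000 draws in which every peak of the second list was moved independently by 10 to 100 kb to either side. This keeps gene-rich and gene-poor regions in place. The fold is the observed number over the mean of the draws, and the two-sided permutation p was adjusted by Benjamini-Hochberg over the 15 pairs. The smallest p these draws can give is 0.002. Shifted peaks do not model promoters or open chromatin as a class, so the fold measures sharing beyond regional density.

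The shares of FLAG-ERG and FLAG-ETV1 peaks that overlap a PC3 JUND or ETV4 peak were compared with those of ETS1 and GABPA by two-sided Fisher's exact tests. Peaks found in both lists of a comparison were left out of both arms, and p was adjusted over the 4 tests per PC3 list. In a second family of 18 Fisher's exact tests, peaks were divided by whether another list shares them. That family, the distances between the midpoints of overlapping peaks (intervals from 2000 bootstrap draws) and the tests on row order were chosen after seeing the data. Peaks are the units of all these tests. With 1 library per factor, a p describes these lists and not factors across cultures.

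The shift test was tested on simulated data made from these lists. With 300 shared peaks planted between simulated ETV4 and JUND lists (3143 peaks in the first), 309 were found against a background of 11.6. With 100 planted between ERG and JUND lists (2314 peaks in the first), 105 were found against 6.07, and with 30 planted between ETS1 and JUND lists (2180 peaks in the first), 36 against 4.77. Of 100 simulated ERG and JUND pairs with no planted overlap, 3 had a p below 0.05. The planted pairs were tested with 200 draws and the pairs without planted overlap with 100. All simulated lists were made by the same random local moves as the draws. The simulation therefore checks the working of the test and not its error rate for real lists that share promoters or open chromatin.

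Regions to be named were chosen by rules fixed before the data were examined. These are the 3 regions present in the most lists for each comparison, with ties going to the most peaks and then the first position, the chromosomes where a list's share was highest and lowest relative to the mean of the 6 lists, and the 3 densest 1 Mb windows of each list. Alternatives were a reciprocal overlap of 50%, a gap of up to 500 bp, peaks set to 400 bp around the midpoint, autosomes only, lists thinned at random to the smallest list (100 draws), 2 other null placements, all peaks kept in both arms, regions with a GABPA peak left out, and 5 Mb windows. Another 3 alternatives were added after seeing the data. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.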

Results

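Binding sites of 5 ETS transcription factors and of JUND, a subunit of the AP-1 transcription factor, were mapped by ChIP-seq in human prostate cells. ETV4 and JUND were profiled in PC3, a line from a metastatic prostate carcinoma. ETS1, GABPA, ERG and ETV1 were profiled in RWPE-1, an immortalised line of non-tumorigenic prostate epithelium. ETS1 and GABPA were precipitated with antibodies against the proteins themselves, and ERG and ETV1 with a FLAG antibody after retroviral expression of FLAG fusions. ERG, ETV1 and ETV4 are among the ETS genes that chromosomal rearrangements activate in prostate cancer. The 6 lists held 27416 peaks. ETV4 made up 11.5% and JUND 10.8% of them, and in RWPE-1 ETS1 made up 7.95%, GABPA 29.4%, FLAG-ERG 8.44% and FLAG-ETV1 31.9%. The median peak width lay between 473 and 490 bp and no peak exceeded 501 bp. Each list came from 1 library, so no value has a replicate error, and sequencing depth is unknown.

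The PC3 lists addressed whether an ETS protein and an AP-1 subunit occupy the same regions in a prostate cancer line. ETV4 and JUND shared 722 regions, which were 22.97% of the ETV4 peaks (95% interval 21.5 to 24.5%) and 24.3% of the JUND peaks (22.8 to 25.9%). Random local shifts gave a mean of 10.01 shared peaks (95% of draws 5 to 16.02), so the overlap was 72.1-fold higher (permutation test, p = 0.002, adjusted p = 0.002, the smallest the draws can give). ETV4 and JUND shared peaks at the highest fold over shifted peaks of the 15 pairs. This was also the only pair with both lists from PC3, so its rank cannot be told apart from a property that lists of that line share. Their overlapping peaks were also the most closely centred, with a median distance between midpoints of 71.3 bp (95% bootstrap interval 62.3 to 80.5 bp) against 240.5 bp after shifting. Midpoints lay within 100 bp of each other in 61.8% of the shared regions, against 20.6% after shifting.

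**Figure D1:**
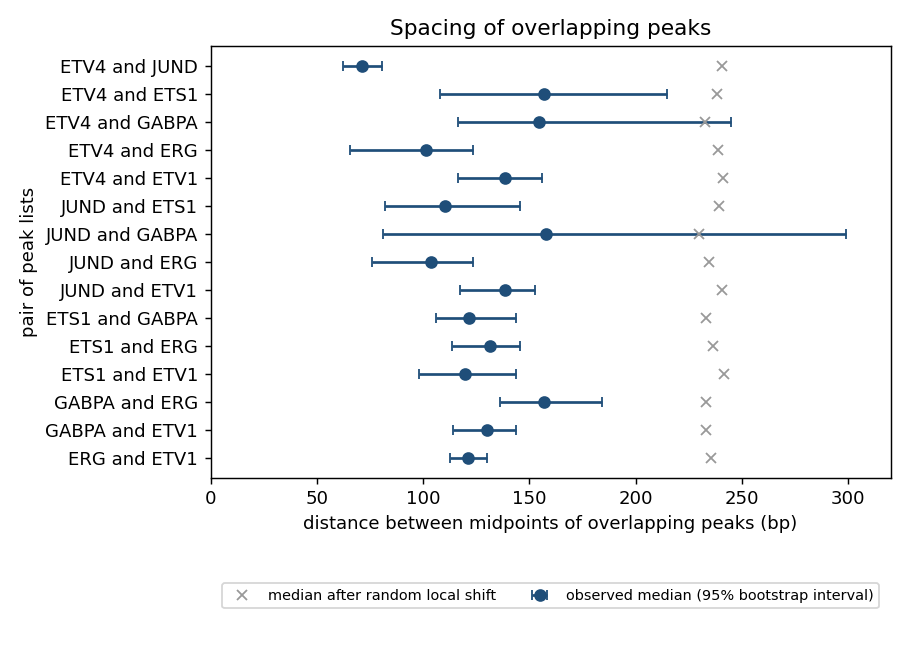
Median distance in bp between the midpoints of overlapping peaks (points, with 95% bootstrap intervals) for each of the 15 pairs of lists, and the median after random local shifts (crosses). The ETV4 and JUND pair has the shortest median, 71.3 bp, while shifted peaks lie between 230 and 241.5 bp.

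ETV4 regions that also carried JUND in PC3 were more often bound by the ectopic ETS proteins in RWPE-1 cells than ETV4 regions without JUND. FLAG-ERG overlapped 14.1% of the 722 ETV4 peaks with JUND (11.8 to 16.9%) and 4.34% of the 2421 without (3.60 to 5.22%; odds ratio 3.63, Fisher's exact test, adjusted p = 3.23e-17). FLAG-ETV1 overlapped 14.7% and 5.99% of them (odds ratio 2.70, Fisher's exact test, adjusted p = 2.08e-12). ETS1 overlapped 3.19% and 1.45% (odds ratio 2.24, exact test, adjusted p = 0.00527). For GABPA the values were 1.25% and 1.45%, which did not pass the test, and the odds ratio of 0.861 had an interval of 0.362 to 1.84. The exact tests did not take the row order of the ETV4 file into account. ETV4 peaks shared with JUND lay on average 38.1% of the way through the file. The mean was 34.2% for FLAG-ERG, 39.7% for FLAG-ETV1, 43.8% for ETS1 and 52.8% for GABPA. A link to JUND itself can therefore not be told apart from a trend along the rows. No region was present in all 6 lists and 11 were present in 5. By position, the first of these lay on chromosome 1 at 59087134 to 59087784 (ETV4, JUND, GABPA, FLAG-ERG and FLAG-ETV1). The next were chromosome 1, 93939607 to 93940332, and chromosome 1, 150287043 to 150287750, each with ETV4, JUND, ETS1, FLAG-ERG and FLAG-ETV1.

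**Figure D2:**
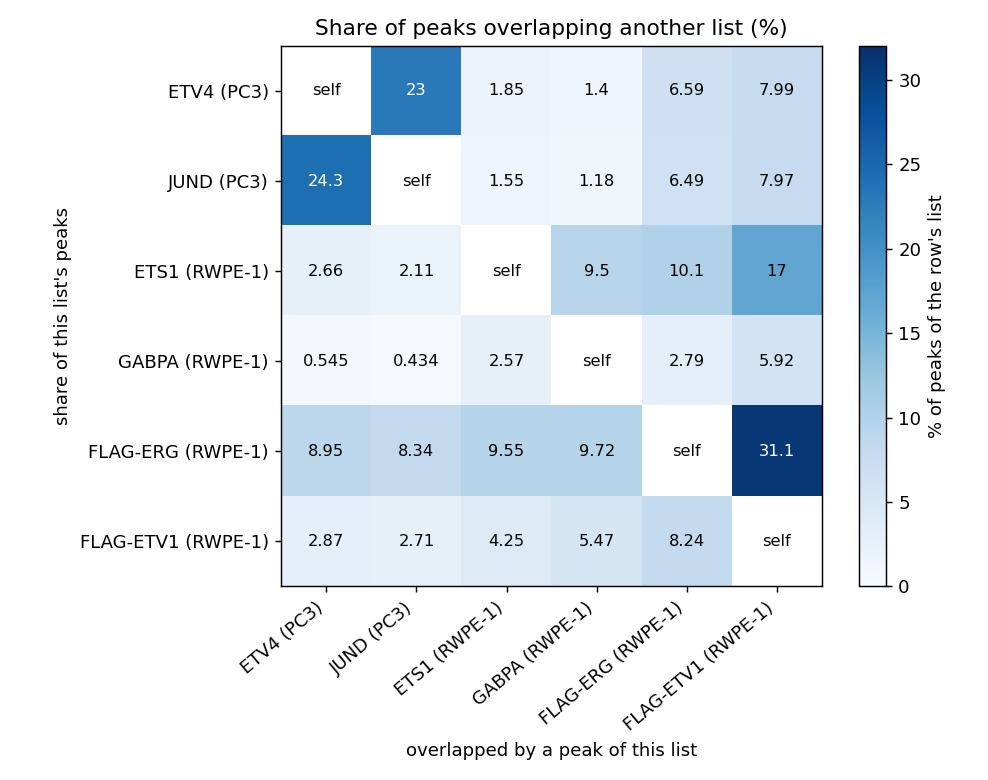
Share in percent of the peaks of each list (rows) that overlap a peak of each other list (columns) by at least 1 bp. The highest shares are the FLAG-ERG peaks overlapped by FLAG-ETV1, 31.1%, and the JUND and ETV4 peaks of PC3 overlapped by each other, 24.3% and 22.97%. This order depends on list size: thinned to the smallest list, FLAG-ERG with FLAG-ETV1 was 7.80% and ETV4 with JUND 16.8%.

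The RWPE-1 lists were then compared with the PC3 JUND list, to ask whether regions of the oncogenic ETS proteins, more than those of endogenous ETS1 and GABPA, were JUND regions. JUND peaks overlapped 8.34% of the FLAG-ERG peaks (7.28 to 9.54%), 2.71% of the FLAG-ETV1 peaks (2.39 to 3.07%), 2.11% of the ETS1 peaks (1.59 to 2.80%) and 0.434% of the GABPA peaks (0.312 to 0.603%). Relative to shifted peaks, the sharing with JUND was 34.9-fold for FLAG-ERG, 14.4-fold for FLAG-ETV1, 9.65-fold for ETS1 and 2.33-fold for GABPA (permutation test, adjusted p = 0.002 for each). Among peaks in only one list of a comparison, JUND overlapped 8.36% of the FLAG-ERG and 1.43% of the ETS1 peaks, an odds ratio of 6.29 (4.18 to 9.79; Fisher's exact test, adjusted p = 3.01e-26). Against GABPA, by the same exact test, the odds ratio of FLAG-ERG was 24.3 (16.6 to 36.6; adjusted p = 1.45e-95) and that of FLAG-ETV1 was 7.05 (4.83 to 10.6; adjusted p = 4.65e-36). FLAG-ETV1 and ETS1 differed little, with 2.67% and 1.77% and an odds ratio of 1.52 (1.04 to 2.29; exact test, adjusted p = 0.0251). That last call of the exact test ended under 6 of the 9 alternative settings that involve these lists, among them the inclusion of all peaks of both lists (odds ratio 1.29, adjusted p = 0.131) and thinning to equal list sizes (1.29, adjusted p = 0.32). JUND was mapped in PC3 and the compared factors in RWPE-1, so these shares concern regions across lines.

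**Figure D3:**
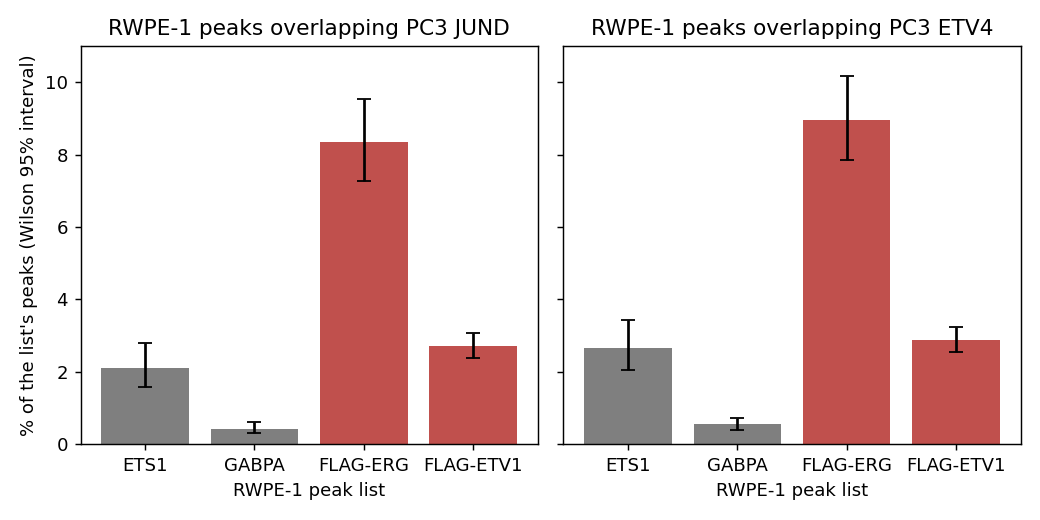
Share in percent of the peaks of each RWPE-1 list that overlap a PC3 JUND peak (left) or a PC3 ETV4 peak (right), with Wilson 95% intervals; grey bars are endogenous ETS1 and GABPA, red bars the FLAG fusions. FLAG-ERG stands highest in both panels, at 8.34% and 8.95%, and GABPA lowest, at 0.434% and 0.545%.

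Taken as shares of each RWPE-1 list, overlaps with the PC3 ETV4 list fell in the same order as those with JUND. ETV4 peaks overlapped 8.95% of the FLAG-ERG peaks (7.85 to 10.2%), 2.87% of the FLAG-ETV1 peaks (2.54 to 3.24%), 2.66% of the ETS1 peaks (2.06 to 3.42%) and 0.545% of the GABPA peaks (0.406 to 0.731%). Taken as shares of the PC3 lists, the larger FLAG-ETV1 list came first, with 7.99% of the ETV4 and 7.97% of the JUND peaks, and FLAG-ERG next, with 6.59% and 6.49%. The overlaps of ETV4 with FLAG-ERG, FLAG-ETV1, ETS1 and GABPA were 40.2-fold, 16.8-fold, 14.9-fold and 3.53-fold over shifted peaks (permutation test, adjusted p = 0.002 for each). Among list-specific peaks the odds ratio of FLAG-ERG was 6.65 against ETS1 (4.39 to 10.4; Fisher's exact test, adjusted p = 1.54e-27) and 22.8 against GABPA (15.9 to 33.7; adjusted p = 4.73e-99). FLAG-ETV1 had an odds ratio of 7.45 against GABPA (5.07 to 11.3; exact test, adjusted p = 7.23e-38) and of 1.67 against ETS1 (1.13 to 2.57; adjusted p = 0.00741). The exact test against ETS1 again lost its call with all peaks of both lists (odds ratio 1.08, adjusted p = 0.665) and with equal list sizes (1.03, adjusted p = 0.705). Of the 207 FLAG-ERG peaks with ETV4, 48.8% also overlapped JUND (42.1 to 55.6%), and of the 251 FLAG-ETV1 peaks with ETV4, 42.2% (36.3 to 48.4%). Of all ETV4 peaks, 22.97% overlapped JUND in PC3. ETV4 peaks shared with FLAG-ERG and FLAG-ETV1 lay nearer the first rows of the ETV4 file, where JUND overlap was higher. The excess over 22.97% can therefore not be told apart from a trend along the rows. Without ETV4, JUND overlapped 4.37% of the 2107 FLAG-ERG peaks (3.57 to 5.33%) and 1.54% of the 8485 FLAG-ETV1 peaks (1.30 to 1.83%), a gap to the peaks with ETV4 that the sharing of ETV4 and JUND within PC3 makes large by itself.

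Within RWPE-1 cells, the 4 ETS lists merged into 19415 regions, of which 92.0% (91.6 to 92.4%) were in 1 list only and 38 were in all 4. FLAG-ERG and FLAG-ETV1 shared 720 peaks, 31.1% of the FLAG-ERG list (29.3 to 33.0%) and 34.5-fold over shifted peaks. ETS1 shared 17.0% of its peaks with FLAG-ETV1 (19.2-fold), 10.1% with FLAG-ERG (30.7-fold) and 9.50% with GABPA (11.9-fold). GABPA shared 5.92% of its peaks with FLAG-ETV1 (8.18-fold) and 2.79% with FLAG-ERG (12.1-fold). Each of these 6 overlaps exceeded the shifted peaks (permutation test, adjusted p = 0.002). The shares depended on list size. With lists thinned to the smallest, FLAG-ERG shared 7.80% of its peaks with FLAG-ETV1. ETS1 then shared 4.21% with FLAG-ETV1, 9.56% with FLAG-ERG and 2.55% with GABPA. GABPA shared 1.46% with FLAG-ETV1 and 2.60% with FLAG-ERG, so FLAG-ERG came before FLAG-ETV1 for both. By position, the first regions in all 4 lists were chromosome 1, 154452664 to 154453386, chromosome 3, 130362603 to 130363190, and chromosome 5, 324323 to 324884. Among regions in more than 1 list, the most frequent combination was FLAG-ERG with FLAG-ETV1 alone, 502 regions, followed by GABPA with FLAG-ETV1 alone, 304 regions.

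Regions of FLAG-ERG and FLAG-ETV1 in common overlapped PC3 JUND peaks more often than those of either protein alone. JUND overlapped 10.8% of the 720 shared peaks (8.77 to 13.3%), 7.21% of the FLAG-ERG peaks without FLAG-ETV1 (6.04 to 8.59%) and 1.98% of the FLAG-ETV1 peaks without FLAG-ERG (1.70 to 2.31%). The shared peaks differed from the FLAG-ERG peaks alone with an odds ratio of 1.56 (1.14 to 2.13; Fisher's exact test, adjusted p = 0.00529) and from the FLAG-ETV1 peaks alone with an odds ratio of 6.001 (4.46 to 8.02; adjusted p = 1.07e-27).

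The distribution of peaks over the genome differed between the lists of PC3 and those of RWPE-1. Chromosome 3 held 9.48% of the ETV4 and 7.43% of the JUND peaks, but 2.80 to 3.86% of the peaks of the RWPE-1 lists. Chromosome 8 held 8.15% and 8.78% in PC3 and 3.72 to 4.80% in RWPE-1. Chromosome 9 held 1.94% and 2.05% in PC3 and 5.73 to 7.41% in RWPE-1. On 14 of 23 chromosomes both PC3 lists lay outside the range of the 4 RWPE-1 lists, 8 above and 6 below. Averaged over all divisions of 6 lists into 2 and 4, the count is 3.07 for any data without ties, so this value is a reference and not a test. The chromosome shares of a list sum to a whole, so the chromosomes are not independent. No test between cell lines was made, since each list is a single library.

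**Figure D4:**
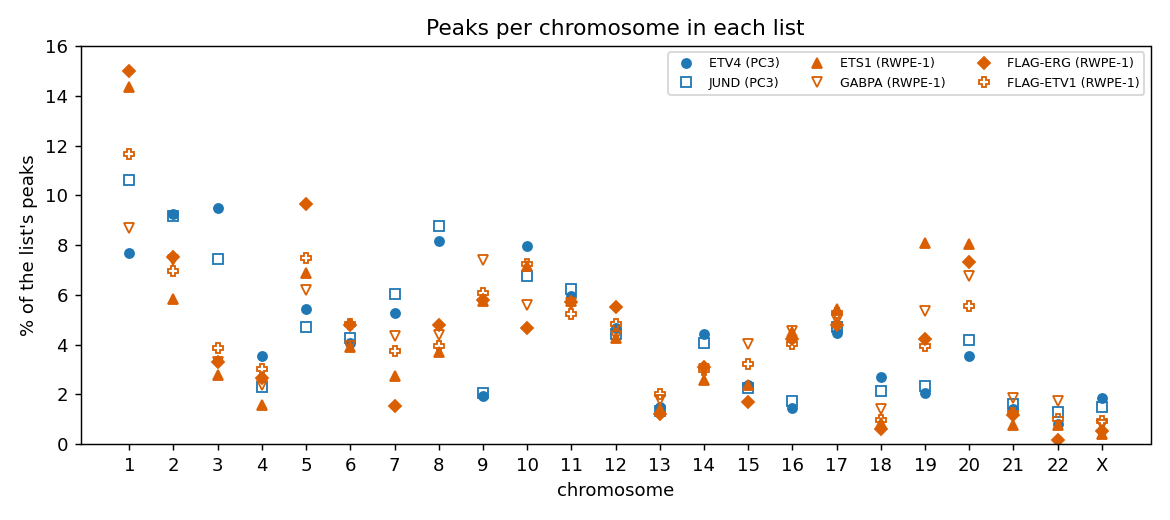
Percent of the peaks of each list on each chromosome, for the PC3 lists (blue) and the RWPE-1 lists (orange). On chromosomes 3, 8 and 18 both PC3 lists lie above all 4 RWPE-1 lists, and on chromosomes 9, 16 and 19 below.

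Relative to the mean of the 6 lists, ETV4 was highest on chromosome 3 (1.89 times) and lowest on chromosome 9 (0.401), and JUND highest on chromosome 8 (1.56) and lowest on chromosome 9 (0.424). ETS1 was highest on chromosome 19 (1.86) and lowest on X (0.418), GABPA highest on 22 (1.77) and lowest on 3 (0.658). FLAG-ERG was highest on chromosome 5 (1.43) and lowest on 22 (0.178), and FLAG-ETV1 highest on 13 (1.30) and lowest on 18 (0.670).

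The densest 1 Mb windows of the PC3 lists were on chromosomes 8 and 10. The ETV4 list had 17 peaks at 33000001 to 34000000 of chromosome 10, where JUND had 15, FLAG-ETV1 7, ETS1 1, and FLAG-ERG and GABPA 0. It had 16 peaks at 36000001 to 37000000 and 15 at 63000001 to 64000000 of the same chromosome. JUND had 17 peaks at 126000001 to 127000000 and 12 at 134000001 to 135000000 of chromosome 8. In RWPE-1, the window at 199000001 to 200000000 of chromosome 1 was the densest for ETS1 (16 peaks), FLAG-ERG (20) and FLAG-ETV1 (27). ETS1 also had 16 peaks at 224000001 to 225000000 of chromosome 1 and 14 at 49000001 to 50000000 of chromosome 19. FLAG-ERG had 16 peaks each at 202000001 to 203000000 of chromosome 1 and 145000001 to 146000000 of chromosome 8. GABPA had 41 peaks in each of the adjoining windows from 60000001 to 62000000 of chromosome 20 and 37 at 136000001 to 137000000 of chromosome 9. FLAG-ETV1 had 25 peaks at 48000001 to 49000000 and 25 at 60000001 to 61000000 of chromosome 20.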

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

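The tests in this part were chosen after the results were seen, apart from the shift test and those on chromosome shares, in which the comparison with the correlation inside RWPE-1 was added afterwards.

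FLAG-ERG and FLAG-ETV1, both expressed in RWPE-1 and precipitated with the same antibody, differed in how often their regions were JUND or ETV4 regions of PC3. Among peaks in only one of the 2 lists, the odds ratio of FLAG-ERG over FLAG-ETV1 was 3.84 for JUND (95% interval 2.98 to 4.95; Fisher's exact test, adjusted p = 1.80e-23) and 3.80 for ETV4 (2.93 to 4.91; adjusted p = 1.69e-22). The FLAG-ETV1 list is the larger, and depth and thresholds are unknown, so its dilution by rarely shared peaks was not excluded. Taken as shares of the PC3 lists, FLAG-ETV1 overlapped 7.97% of the JUND and 7.99% of the ETV4 peaks. FLAG-ERG overlapped fewer, 6.49% and 6.59%. The odds ratios of FLAG-ERG over FLAG-ETV1 were not run under the alternative settings.

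The JUND share of the FLAG-ERG list, 8.34% (7.28 to 9.54%), stood above those of ETS1 and GABPA. Dilution of the GABPA list by rarely shared peaks, as the whole cause, is argued against by the peaks that FLAG-ETV1 shares. JUND overlapped 0.837% of these in the GABPA list (0.326 to 2.13%), against 10.8% in the FLAG-ERG list (8.77 to 13.3%). JUND overlapped 3.77% of the ETS1 peaks shared with FLAG-ETV1 (2.26 to 6.23%), also below the FLAG-ERG list. For these peaks, that argues against dilution of the ETS1 list as the whole cause. For ETS1 peaks shared with FLAG-ERG or FLAG-ETV1 the JUND share was 4.91% (3.30 to 7.27%). Of the 46 ETS1 peaks with JUND, 28 lay outside the 221 shared with FLAG-ERG and the others within them. Those 221 peaks overlap FLAG-ERG peaks by selection, so their JUND share cannot decide on dilution of the ETS1 list. Regional density is argued against as well, since moving the FLAG-ERG peaks left 5.53 overlapped JUND peaks on average against 193 observed. Of the 193 JUND-overlapping FLAG-ERG peaks, 40.4% were also in the larger FLAG-ETV1 list. JUND still overlapped 7.21% of the 1594 FLAG-ERG peaks without FLAG-ETV1 (6.04 to 8.59%), against 2.11% of the ETS1 list (1.59 to 2.80%). This argues against peaks called in both FLAG lists as the whole cause. A background of the FLAG antibody was not excluded, since antibody and ectopic expression coincide and depth and thresholds are unknown. A difference between the oncogenic and the endogenous proteins, which the design names, also stays open and was not separated from the antibody. It did not extend evenly to FLAG-ETV1, whose odds ratio over ETS1 for JUND, 1.52, did not hold under several alternative settings.

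The rows of the files are in an order that the labels do not describe, and in 14 of 30 trends tested (10000 permutations each) the position of a peak in its file went with its overlap, in 13 of them towards the first rows and in 1, that of ETS1 peaks with JUND, towards the last. Of the 20 trends in the ETV4, JUND, ETS1 and GABPA files, 13 passed the test and 7 did not, among them ETV4 with GABPA (permutation test, adjusted p = 0.7) and ETV4 with ETS1 (adjusted p = 0.2). In the first 20% of rows, FLAG-ERG overlapped 14.1% of the ETV4 peaks, 10.9% of the JUND peaks and 6.88% of the GABPA peaks, and GABPA overlapped 17.4% of the ETS1 peaks (permutation test, p = 0.0002, the smallest these draws can give, and adjusted p = 0.0005 for each trend). JUND overlapped 41.7% of the first and 13.5% of the last 20% of the ETV4 rows. In the FLAG-ETV1 file the one trend past the threshold was that of ETS1 (permutation test, adjusted p = 0.04). ETS1 overlap in its successive parts of 20% of rows was 4.52%, 5.32%, 4.46%, 3.38% and 3.55%. No trend passed in the FLAG-ERG file. Sorting by genomic position is argued against, since the largest absolute rank correlation of row and position was 0.0380; sorting by peak strength cannot be told from the files, in which 0 columns hold a strength.

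The chromosome shares of the PC3 and the RWPE-1 lists differed on 14 of 23 chromosomes without overlap. The same peaks entering several lists is argued against, since 13 of these chromosomes kept their direction when only peaks found in a single list were counted. All correlations below also counted only peaks found in a single list. For a property of each cell line that acts on every factor, 22 autosomes were compared: log2 of ETV4 over ETS1 and log2 of JUND over GABPA correlated with Pearson r = 0.830 (permutation adjusted p = 0.00025 over 5 correlations; 0.764 without the 2 most extreme chromosomes) and Spearman rho = 0.802 (adjusted p = 0.00025), and the other 3 pairings of the lists gave r of 0.803, 0.725 and 0.560, the last falling to 0.407 without the 2 most extreme chromosomes, with a rho of 0.738. Inside RWPE-1, FLAG-ERG over ETS1 and FLAG-ETV1 over GABPA also correlated (r = 0.549, permutation adjusted p = 0.0054; 0.378 without the 2 most extreme chromosomes; rho = 0.462). Each of the 4 pairings between the lines exceeded this, by 0.0116 (bootstrap interval -0.551 to 0.783) to 0.282 (-0.0146 to 0.773) in r and by 0.261 (-0.106 to 0.649) to 0.346 (-0.0783 to 0.775) in rho, and the intervals of all 8 differences included 0, so over 22 autosomes these correlations leave open whether the cell line is what the factors share. A property of the cell line, such as DNA copy number or chromatin state, stays open, since the input libraries were not analysed here.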

How the results depend on the processing

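No paired analysis was possible because each factor has 1 library and no replicate number, and for the same reason no replicate could be left out. The stricter threshold by score was not run, since the lists hold no score, nor were the promoter, motif and gene list analyses. Of 139 alternative values for the 15 overlaps, counting only settings that involve the lists of a pair, 137 kept their direction and their side of the threshold. The exceptions were ETV4 with GABPA in the first 50% of rows of 4 files (0.446% of ETV4 peaks, 2.04-fold over moved peaks against 3.53-fold with all rows, permutation test, adjusted p = 0.108) and JUND with GABPA in the first 20% of the GABPA rows (0.235% of JUND peaks, 2.13-fold against 2.33-fold, adjusted p = 0.0979). Both settings were chosen after seeing the data, as was leaving out peaks with neighbours, and the cut of the GABPA list lowers the share of JUND peaks by construction. The share of ETV4 peaks with JUND ranged from 16.8 to 23.7%, and its fold over moved peaks, 72.1 as reported, from 36.2 (gap of up to 500 bp) to 206 (circular shift), with 42.0 for a local shift of 2 to 20 kb; it was the highest of the 15 pairs in each of these settings. The folds of JUND with the RWPE-1 lists moved too, from 18.5 to 77.8 for FLAG-ERG and from 7.63 to 26.4 for FLAG-ETV1. For ETS1 they went from 5.14 to 20.3 and for GABPA from 2.05 to 4.23. The odds ratios of FLAG-ERG over ETS1 ranged from 4.22 to 14.9 for JUND and from 3.59 to 8.33 for ETV4, and those of FLAG-ERG over GABPA from 15.3 to 35.2 and from 13.8 to 71.4. Those of FLAG-ETV1 over GABPA ranged from 4.26 to 10.1 for JUND and from 5.26 to 14.4 for ETV4. All of these odds ratios were past the threshold in the settings run. FLAG-ETV1 over ETS1 did not hold. For JUND its odds ratio missed the threshold with reciprocal overlap (1.48), a gap of up to 500 bp (1.22), peaks without neighbours within 10 kb (1.33), all peaks (1.294 for both lists in full), GABPA regions left out (1.45) and equal list sizes (1.293). For ETV4 it missed with the first 50% of rows (1.57), peaks without neighbours (1.05), all peaks (1.08) and equal list sizes (1.03). The cause was not tested. The share of RWPE-1 regions in 1 list only was 93.9% with reciprocal overlap and 90.7% with a gap of up to 500 bp. In 5 Mb windows, larger by construction, the densest window held 1.40% of the ETV4, 1.35% of the JUND, 2.25% of the ETS1, 2.03% of the GABPA, 2.51% of the FLAG-ERG and 0.904% of the FLAG-ETV1 list.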

Other observations

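ETS1 regions in RWPE-1 cells fell into groups that differed in overlap with PC3 JUND peaks. None of the 207 ETS1 peaks shared with GABPA overlapped a PC3 JUND peak, so that 3 counts would be 1.45% and the Wilson upper bound is 1.82%, while 46 of the 1973 other ETS1 peaks did (2.33%, 1.75 to 3.10%; Fisher's exact test, adjusted p = 0.0212). At the share of those other peaks, 4.83 would have been expected. The exact test ignored row order: ETS1 peaks with GABPA lay on average 37.3% of the way through the file and those with JUND 61.4%. A link to GABPA itself can therefore not be told apart from a trend along the rows. For ETV4 the test did not pass, and it was not compared with that for JUND: ETV4 overlapped 3.86% of the ETS1 peaks with GABPA (1.97 to 7.44%) and 2.53% of those without (odds ratio 1.55, interval 0.624 to 3.35, exact test, adjusted p = 0.269). ETS1 peaks that FLAG-ERG or FLAG-ETV1 also bound overlapped a PC3 JUND peak in 4.91% of 468 cases (3.30 to 7.27%) against 1.34% of 1712 (odds ratio 3.79, exact test, adjusted p = 2.00e-05). They overlapped a PC3 ETV4 peak in 8.76% against 0.993% (odds ratio 9.56). These tests were chosen after the data were seen.

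The GABPA list held the highest share of regions found in no other list. This was 90.8% of its peaks, against 82.8% for FLAG-ETV1, which is larger, and 54.1% for FLAG-ERG. Taken in successive parts of 20% of rows, GABPA peaks overlapped FLAG-ETV1 15.3-fold, 5.87-fold, 5.93-fold, 6.61-fold and 6.99-fold over shifted peaks. For this partner the first part stood apart and the others showed no decline. With FLAG-ERG the folds were 27.6, 10.3, 8.66, 3.71 and 8.71, and with ETS1 24.5, 10.5, 7.51, 7.57 and 7.88. The first part stood apart for both. The lower folds after the second part rest on small counts and do not show a further decline. Shared peaks in the second and last parts were 35 and 34 with FLAG-ERG, and 30 and 34 with ETS1. For JUND the first part did not stand apart, at 2.11-fold against 3.36-fold in the last. Along the ETS1 rows the partners ran in opposite directions: GABPA overlap fell from 17.4% in the first 20% of rows to 4.13% in the last, while JUND overlap was 0.917% in the first and 2.98% in the last. The mean position of ETS1 peaks shared with JUND was 61.4% of the way through the file (permutation test, adjusted p = 0.02) and that of peaks shared with GABPA was 37.3% (adjusted p = 0.0005).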
